A study of Macaca mulatta with 4 samples.

How the data were processed

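Peripheral blood mononuclear cells (PBMC) of 4 rhesus macaques, taken before and after transplantation of porcine islets, were thawed, marked with oligonucleotide tags, pooled and captured with a droplet-based 3' kit from 10x Genomics, per the labels' protocols. The 4 animals of a time point shared 1 library, so 2 libraries held 8 specimens, and the library and the time point cannot be told apart. The deposited values are whole UMI counts per gene and cell barcode, split by tag into 1 matrix per specimen. These counts were made with cellranger 7.1.0, per the file headers, against the macaque build Mmul_10, per the submitters' processing notes. The annotation release and the filter that separated cells from empty droplets are not given in the sources used here. A deposited table gave the specimen of each tag, and the specimen was taken from it and from the tag calls per barcode. Tag counts were left out of all gene totals. Genomic positions were not used here.

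The feature table held 26530 genes, of which 16678 had a name, and a table of gene names supplied 564 further names, giving 17242 named genes. A total of 140 names were shared by more than 1 gene identifier and were kept apart by identifier. Of 60535 deposited cell barcodes, 60283 had at least 300 genes and at most 10% of UMIs from the 13 mitochondrially encoded genes. Doublets of 2 animals carry several tags and were not in the matrices. Doublets within an animal were scored with Scrublet (scanpy 1.11.5), whose automatic threshold marked nearly no cells of the pre-transplantation library. The number removed per specimen was therefore set to the rate expected from the barcodes with several tags (7030 of 39470 before and 7170 of 35265 after transplantation), which took out 4967 cells, 4.98% to 10.3% per specimen, and left 55316.

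Counts of each cell were scaled to 10000 and log-transformed, and 2000 variable genes without ribosomal protein and mitochondrial genes gave 30 principal components. A neighbour graph took 4 neighbours of each cell from each of the 8 specimens, and Leiden clusters were found at resolution 1.0 (igraph 0.11.9, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). A cluster was named from a fixed set of marker genes by those among its top 10 genes by fold, and a name needed at least 3 markers at 1.5 times the level of the other clusters. The scoring rule was set after the clusters were seen. Cells of the B class were clustered again in the same way. Conventional and plasmacytoid dendritic cells lay in 1 cluster and were tested together, no cluster was named memory-like, and 2 of the CD4 T-like clusters, which are led by naive T cell genes, also held naive CD8 T cells. B class clusters led by T cell or platelet genes were set aside as mixed (1.84% of cells before and 0.150% after), and a cluster led by IGFBP2, RTKN2 and TRGV10 stayed unnamed (4.19% and 2.37%).

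The replicate was the animal, and all tests were two-sided. Shares of cells per animal were compared by exact permutation tests over the 70 assignments of 4 and 4 values (scipy 1.17.1), with Benjamini-Hochberg adjustment over 9 PBMC classes or 6 B cell subsets. Here and in all exact permutation tests below, the assignments leave the pairing of specimens by animal aside. Within the pairing, 4 animals are too few for an exact p under 0.05. For shares of cells with a UMI, each cell was thinned to 500 UMIs, which left out 0 of 5500 B cells before and 0 of 5575 after transplantation. UMI counts were summed per animal and class where an animal had at least 20 cells, filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3, quasi-likelihood test, adjusted p under 0.05). Mean log2 CPM values of gene lists use a prior count of 2, and CPM values of single genes use none. Gene lists with at least 4 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 238 tests of 34 lists and 9 classes. No list passed with an estimated correlation, which also uses the residual degrees of freedom of the fit (6, or 5 in CD16 monocyte-like cells with 7 specimens), and 45 had an unadjusted p under 0.05 there. The list of ribosomal protein genes was set by a name rule that also took 7 kinase genes. Figures were drawn with matplotlib 3.10.9.

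Groups, tests, marker genes, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took in B cells the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, an average log2 CPM of at least 5, a symbol, no ribosomal or mitochondrial origin and no overlap of the 4 values after with the 4 values before. In each other class it took 5 rises and 5 falls. A fixed set of 14 B cell genes and TNFSF13B in CD14 monocytes were named whatever their values, as were up to 4 members with the smallest p of each described list. A few of the genes so named are not reported here, and they remain in the counts given. Alternatives were a minimum of 500 genes, no doublet removal, resolutions 0.5 and 2.0, an ordinary neighbour graph, a marker score per cell, RLE scaling, DESeq2 1.42.0, no filter on genes, cells thinned or not, each specimen left out, and the animal as a block. Chosen after seeing the data were Scrublet's automatic threshold, B cells of clusters with 20% to 80% of their cells from each time point, CD14 monocytes without a shallow cluster or without cells carrying at least 3 B cell UMIs or 2 T cell UMIs, and each specimen left out of the list tests. For the depth of CD14 monocytes with B cell UMIs, as many cells were drawn 1000 times per animal by depth alone, with Poisson B cell UMIs at a constant rate per UMI and all CD14 monocytes of the animal as the pool. This comparison, also chosen after seeing the data, replaced a bound of 1.5 times the median UMIs, which all 4 animals had passed.

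The same animals were sampled at both times, so the animal pairs the specimens. Deviations from the time point means correlated between the 2 specimens of an animal at 0.121 to 0.434 over genes, and the animal's own other specimen gave the highest correlation in 35 of 35 pairs of animal and class. Specimens of a time point differed by a chi-square per degree of freedom of 30.4 to 65.5 over 12 pairs, so none was a copy of another. Simulated counts had 200 changed genes per class, drawn only from genes with an average log2 CPM of at least 5. Gene numbers in parentheses below count all genes in the step. The test was checked on these counts, so its recovery of less expressed genes was not measured. Of 2-fold changes it recovered 79% in B cells (8632 genes), 66% in atypical memory-like B cells (2481), 71% in naive-like B cells (5564), 93% in CD4 T cells (9025), 67% in CD8 T cells (7285), 62% in NK cells (3788), 48% in CD14 monocytes (7909), 59% in CD16 monocytes (6297) and 31% in dendritic cells (3534). Of 4-fold changes it recovered 82% in dendritic cells and 87% in atypical memory-like B cells, the lowest values. Unchanged genes made up 1.65% of the calls in B cells, 7.27% in atypical memory-like, 9.04% in naive-like, 4.48% in CD4 T, 7.73% in CD8 T, 6.10% in NK, 8.86% in CD14 monocyte-like, 5.95% in CD16 monocyte-like and 4.24% in dendritic-like cells, above the 5% set by the threshold in 6 classes. Each class had a single simulated set without pairing by animal. A single draw cannot show whether the expected share in a class exceeds 5%.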

Results

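Single-cell RNA profiles were measured in PBMC, the lymphocytes, monocytes and dendritic cells of blood, from 4 rhesus macaques named R175, R176, R178 and R182. Each animal was sampled before (pre) and after (post) it received pig pancreatic islets under an immunosuppressant regimen that included belimumab, an antibody against the B cell survival cytokine BAFF. The interval between the samples is not given in the sources used here. The study asked how the immune cells of blood, and CXCR5-carrying atypical memory B cells among them, differed after treatment. The pre-transplantation specimens held 30023 cells after filtering and the post-transplantation specimens 25293, with a median of 1889 and 1821 UMIs per deposited cell. Gene UMIs per specimen before transplantation came to 23371425 in R175, 20658023 in R176, 17266551 in R178 and 16126939 in R182. After transplantation they came to 19352054, 18401364, 16383922 and 5808440 in the same order, and post R182 was also the shallowest specimen per cell, with a median of 1269 UMIs. All specimens of a time point came from the same library, so each difference below is also a difference between 2 libraries.

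NK cells, cytotoxic innate lymphocytes, made up 6.98% ± 3.35 of cells before and 1.73% ± 0.469 after transplantation (SD, n = 4 animals), and were lower after it in 4 of 4 animals. CD14 monocyte-like cells, the classical monocytes of blood, made up 6.67% ± 2.54 and 17.0% ± 4.96 and were higher in 4 of 4 animals. For each of these classes the exact permutation test gave p = 0.0286, the smallest p that 4 against 4 allows with the pairing by animal left aside. The adjusted p was 0.129 over 9 classes, so neither passed the threshold, which over 9 classes only a p shared by most of them can do. With the animal as a block, limma on logit shares placed the NK cell decrease past it, with a change of -1.36 and an adjusted p = 0.0276. B cells made up 17.7% ± 7.77 before and 21.4% ± 9.62 after (exact permutation p = 0.600), with 27.2% and 23.5% in R175, 16.8% and 33.3% in R176, 8.23% and 10.2% in R178, and 18.5% and 18.7% in R182. CD4 T cells held 40.1% ± 7.87 and 35.4% ± 7.58 (exact permutation p = 0.457), CD8 T cells 17.2% ± 7.01 and 13.2% ± 5.83 (p = 0.371), CD16 monocyte-like cells 2.92% ± 2.42 and 5.57% ± 4.52 (p = 0.371) and dendritic-like cells 0.877% ± 0.378 and 1.37% ± 0.755 (p = 0.286). The CD16 monocyte-like difference of 2.66 points was 0.772 without post R178 and 4.45 without post R182. The dendritic-like difference of 0.489 was 0.228 without post R176 and 0.779 without post R175. Platelet-like cells (0.953% and 0.996%) and cycling cells (0.508% and 0.836%) were rare at both times. Of the CD14 monocyte-like cells, 503 lay in a cluster with a median of 625 UMIs per cell, of which 3.98% came from the pre-transplantation library. Without that cluster the class made up 6.60% ± 2.53 before and 14.5% ± 5.90 after (exact permutation p = 0.0857), higher in 3 of 4 animals and lower in R182, with 9.46% and 7.22%.

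**Figure D1:**
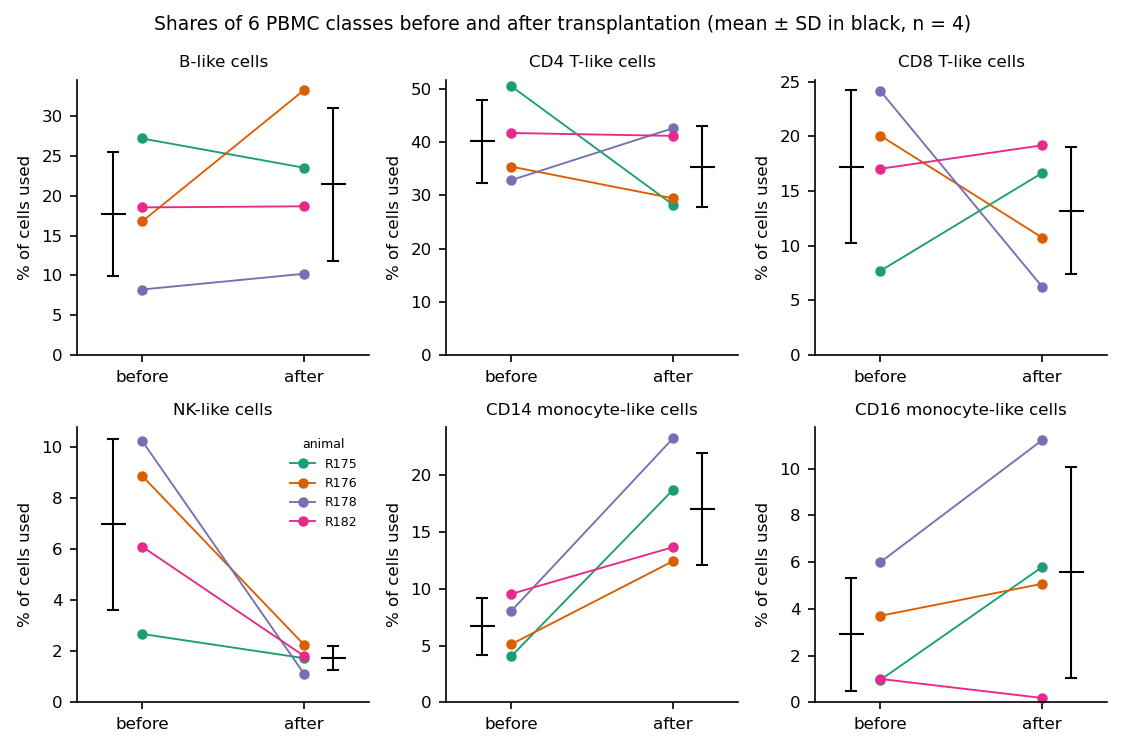
Share of each animal's cells (vertical axis, percent) in 6 classes before and after transplantation, with a point per animal, lines joining the same animal, and the mean ± SD in black (n = 4). NK cells averaged 6.98% before and 1.73% after, and CD14 monocyte-like cells 6.67% and 17.0%.

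Within the B cells, a cluster of 1758 cells with JCHAIN, the joining chain of secreted IgM and IgA, SSPN, TEX9 and THY1 among its top genes made up 5.67% ± 1.82 of B cells before and 27.8% ± 6.19 after transplantation (SD, n = 4), and was larger in 4 of 4 animals. JCHAIN is in the plasma cell marker set and SSPN in the memory set, but this cluster did not meet the naming rule for any set and stayed unnamed. The difference in share passed the threshold (exact permutation p = 0.0286, adjusted p = 0.0429 over 6 subsets; adjusted p = 2.78e-05 in limma with the animal as a block). Of its 8 defining genes that could be tested in the remaining B cells, 0 differed there in edgeR after adjustment, and 2 had an unadjusted p under 0.05. Within the naive-like cells, however, which lay outside the cluster, JCHAIN rose by 1.44 (SE 0.26, edgeR adjusted p = 0.00483), so the size of the cluster is not free of that rise. Only 17.5% of its cells came from the pre-transplantation library, so the cluster may be a feature of the other library rather than a cell type. Its adjusted exact permutation p was 0.0571 without each of pre R175, R176, R178 and R182 and post R175, R176, R178 and R182, while its own exact permutation p stayed at 0.0286. The adjusted value moved because 4 of the 6 subsets shared that p with all specimens and 3 with a specimen left out.

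Naive-like B cells made up 41.0% ± 16.4 of B cells before and 38.8% ± 16.1 after transplantation (SD, n = 4, exact permutation p = 0.943). Different clusters held them at the 2 times. Cluster 3, led by WIF1, CD9 and FCER2, the low-affinity IgE receptor, held 36.1% and 11% of B cells, and cluster 6, led by VPREB3, held 4.91% and 27.7%. The atypical memory-like cluster was led by CST7, RGS16 and TOX2 and carried ITGAX, the integrin CD11c of atypical and age-associated B cells. It made up 16.6% ± 11.1 of B cells before and 10.1% ± 5.56 after (exact permutation p = 0.343, adjusted p = 0.411), with 30% and 14.8% in R175, 5.62% and 5.69% in R176, 9.45% and 4.83% in R178, and 21.2% and 15% in R182. Of its 7 defining genes that could be tested outside it, RGS16, CST7 and TOX2 were lower there after transplantation, and AREG and CD9 of cluster 3 likewise, so the sizes of these clusters are given without a direction. Activated-like clusters, with EGR1, NFKBID and NR4A3 among their top genes, and 2 further unnamed clusters also had defining genes that differed outside them. Their sizes were tested among the 6 subsets, with an exact permutation p = 0.0286 each that entered the adjusted p of the JCHAIN-expressing cluster, but are not read as changes of cell types.

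CXCR5, the chemokine receptor that guides B cells into follicles (ENSMMUG00000009316), was lower in B cells after transplantation in 4 of 4 animals. After each cell was thinned to 500 UMIs, 5.71% ± 1.12 of B cells carried a CXCR5 UMI before and 3.1% ± 0.617 after (SD, n = 4, exact permutation p = 0.0286). Without thinning the shares were 21.0% and 7.21% (exact permutation p = 0.0286). In summed counts CXCR5 fell by 1.11 (SE 0.20) on the log2 scale, from 121 to 55.4 CPM (edgeR adjusted p = 0.0159). The edgeR call was lost without post R178 (adjusted p = 0.0555) and in B cells of clusters shared by both time points (log2 fold change -0.98, adjusted p = 0.105). CD8 T cells, which mostly lack CXCR5, carried a UMI in 0.403% and 0.150% of unthinned cells, at median depths of 1478 and 1515 UMIs against 1855 and 1418 in B cells.

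In the atypical memory-like cluster, 4.52% ± 2.24 of thinned cells carried a CXCR5 UMI before and 1.11% ± 1.18 after transplantation (SD, n = 4), lower in 3 of 4 animals (exact permutation p = 0.0571). The share moved past the threshold without pre R175 (difference -4.10 points, exact permutation p = 0.0286) and without thinning, where it was 15.3% before and 6.46% after (exact permutation p = 0.0286). These shares rest on 17 of 699, 3 of 76, 2 of 50 and 21 of 273 cells before and on 7 of 252, 1 of 141, 0 of 34 and 1 of 103 cells after, in R175, R176, R178 and R182. Summed counts of the cluster gave a log2 fold change of -1.0 (SE 0.44, edgeR adjusted p = 0.495), and the naive-like cells -0.56 (SE 0.24, adjusted p = 0.167). CXCR5-carrying cells of the cluster made up 0.740% ± 0.630 of thinned B cells before and 0.149% ± 0.185 after (exact permutation p = 0.0857). In CD14 monocyte-like cells, taken as background, a CXCR5 UMI was present in 0.846% of thinned cells before and 0.00% after (exact permutation p = 0.0286), and these cells also carried B cell transcripts before transplantation, as given below. In pre R182, however, 35 of 605 such cells without any B cell UMI carried a CXCR5 UMI (5.79%, not thinned). In summed counts of these monocytes CXCR5 had a log2 fold change of -5.90 (SE 0.56, edgeR adjusted p = 0.0032).

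A cluster-free measure counted B cells with a UMI of at least 2 of 6 atypical memory markers, TBX21, ITGAX, FCRL5, FCRL3, ZEB2 and SOX5. It gave 1.45% ± 0.400 of thinned B cells before and 1.12% ± 1.48 after transplantation (SD, n = 4, exact permutation p = 0.771). Post R182 stood at 3.34% against 0.284% to 0.444% in the other post specimens, and without it the difference was -1.07 points (exact permutation p = 0.0571). Post R175 and post R182 had nearly the same share of B cells in the atypical memory-like cluster. After transplantation the measure in thinned cells therefore did not follow the size of that cluster. Without thinning the shares were 13.1% ± 5.49 and 4.55% ± 2.24 (exact permutation p = 0.0571), with the depth difference named above. The same measure in thinned CD14 monocyte-like cells gave 0.679% ± 0.569 and 0.346% ± 0.160, at median depths of 3287 and 2791 UMIs. These cells carried B cell transcripts before transplantation, and whether they express the 6 markers themselves was not tested. Their shares are therefore not a floor for the B cell values.

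**Figure D2:**
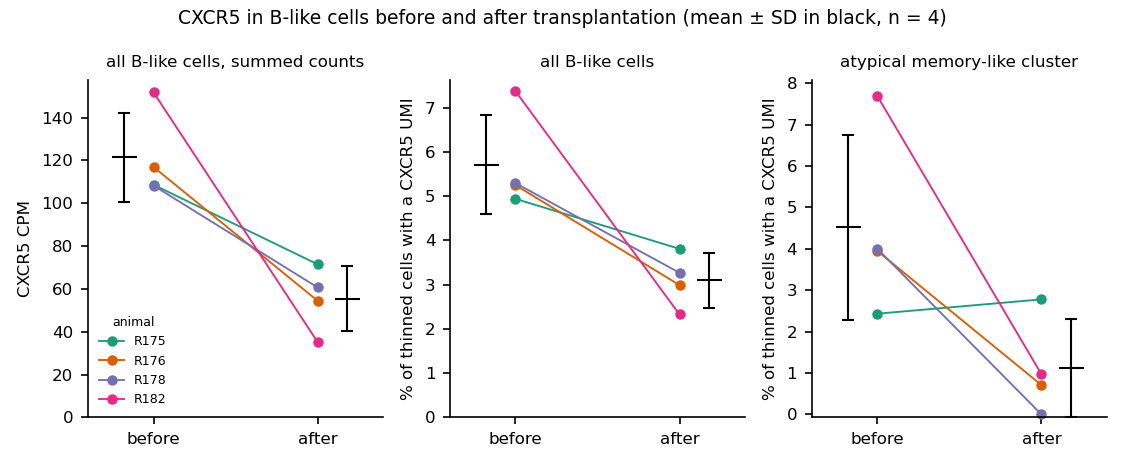
CXCR5 before and after transplantation, as CPM of summed counts in all B cells and as the percent of cells thinned to 500 UMIs that carried a CXCR5 UMI, in all B cells and in the atypical memory-like cluster. Points are animals, lines join the same animal, and black marks give the mean ± SD (n = 4), which fell from 5.71% to 3.1% of thinned B cells.

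B cells as a whole expressed less of several genes that are switched on within hours of stimulation. CD83, a surface molecule of activated B cells, fell by 2.21 (SE 0.34) on the log2 scale, from 682 to 145 CPM, CD69, an early activation antigen, by 1.85 (SE 0.34), from 2759 to 760 CPM, and EGR2, a transcription factor induced by antigen receptor signalling, by 2.34 (SE 0.32). Further falls were those of NFKBID, a nuclear regulator of NF-kB (-2.73), the stress-induced factor ATF3 (-2.63), the histone demethylase KDM6B (-2.08), the NF-kB inhibitor TNFAIP3 (-1.97), the nuclear receptor NR4A1 (-1.77), and SKIL, a repressor of TGF-beta signalling (-1.77). Among genes with an average log2 CPM of at least 5 and no overlap of the values before and after, the deepest fall was that of CD9, a tetraspanin, by 3.04 (SE 0.34), from 111 to 13.8 CPM. Rises were led by CFD, complement factor D (log2 fold change 1.61), the TRAF3-binding adaptor TRAF3IP3 (1.45), AIM2, a sensor of cytosolic DNA (1.38), EAF2 (1.25), the antiviral deaminase APOBEC3G (1.24) and LMO2, a factor expressed in germinal centre B cells (1.24). BEND5 (1.18), SUSD3 (1.11), TAF12 (1.1) and PTGES3, a co-chaperone of HSP90 (1.07), completed the 10 largest rises under the same limits.

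In edgeR, 270 of 8839 tested genes passed in B cells, 113 higher and 157 lower after transplantation, with adjusted p values of the genes just named from 0.00209 to 0.0349 (n = 4 per time point). With the animal as a block 955 genes passed, 375 higher and 580 lower, among them all 270. TNFRSF13C, the BAFF receptor, rose by 0.96 (SE 0.22, adjusted p = 0.0366), from 19.4 to 36.3 CPM. TNFRSF13B, which encodes the BAFF and APRIL receptor TACI, had a log2 fold change of 0.67 (adjusted p = 0.311), and passed with the animal as a block (0.65, adjusted p = 0.0305). No call was made for CD74 (-0.51), ZEB2 (-0.48), ITGAX (-0.60), TCL1A (-0.62), BCL2 (-0.27), CD86 (0.17) or FCRL5 (-0.09), with adjusted p from 0.125 to 0.903, TBX21 and TNFRSF17 were too low to test, and CD27 had no matching name. Of these, CD74 passed with the block (-0.51, adjusted p = 0.00991). Leaving out a specimen gave 207, 120, 107 and 321 genes without pre R175, R176, R178 and R182, and 152, 90, 50 and 135 without post R175, R176, R178 and R182. Of the genes named for B cells, 5, 9, 12 and 3 lost the call in that order before transplantation (highest adjusted p 0.101, 0.114, 0.0851 and 0.0600), and 11, 12, 18 and 13 after it (0.106, 0.118, 0.135 and 0.0917). Among them were TNFRSF13C, lost without pre R175 or R182 and without each post specimen (up to 0.115), ATF3, AIM2, CD69, TNFAIP3 and APOBEC3G, while the other 15 of the 20 genes named by size kept it. CFD lost it without doublet removal (0.81, adjusted p = 0.362). Thinned cells gave 94 genes (86 shared), and clusters with cells of both time points 28 (27 shared), where TNFRSF13C had 0.50 (adjusted p = 0.549).

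**Figure D3:**
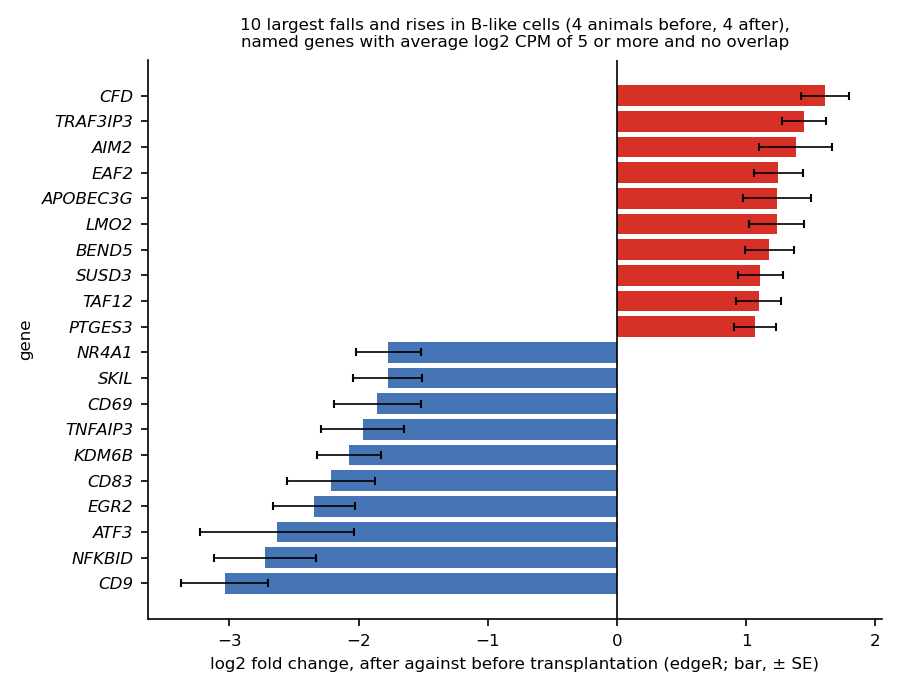
Log2 fold change, post over pre, of the 10 largest falls and 10 largest rises in B cells (horizontal axis) among named genes with an average log2 CPM of at least 5 and no overlap of the values before and after, with bars for the edgeR estimate and whiskers for its SE (n = 4 animals per time point). Values run from -3.04 for CD9 to 1.61 for CFD.

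Among the fixed gene lists, B cell activation genes fell together: 8 of 18 measured members passed over all genes and 9 when adjusted over the list alone, all lower, with a median log2 fold change of -0.86 (camera adjusted p = 3.52e-12; adjusted p = 0.0548 with an estimated correlation). NR4A3, a nuclear receptor induced by antigen receptor signalling, fell by 3.29 (SE 0.40, adjusted p = 0.00209). Immediate-early genes, the AP-1 factors and their partners, fell as well, with 7 of 18 members lower (13 adjusted over the list alone), a median of -0.93 and a camera adjusted p = 3.73e-12 (adjusted p = 0.213 with an estimated correlation). Among them were KLF4 (-1.84) and FOSB (-1.76). TNF and NF-kB response genes had 5 of 18 members lower (10 lower and 1 higher adjusted over the list alone; median -0.90, camera adjusted p = 3.0e-07; adjusted p = 0.152 with an estimated correlation). These included the inhibitor NFKBIA (-1.48). NFAT targets had 4 of 9 lower (4 adjusted over the list alone; median -1.32, camera adjusted p = 5.27e-06; adjusted p = 0.152 with an estimated correlation). These included NR4A2 (-1.49). The NFAT list shares NR4A1, NR4A3 and EGR2 with the B cell activation list. Genes of noncanonical NF-kB signalling and survival had 3 of 14 lower (5 adjusted over the list alone; median -0.43, camera adjusted p = 0.000625; adjusted p = 0.176 with an estimated correlation), namely the antiapoptotic MCL1 (-0.97) and BCL2A1 (-0.94) and the subunit gene NFKB2 (-1.09). Heat shock genes, chaperones of stressed cells, had 0 of 10 members past in edgeR over all genes (6 at an unadjusted p under 0.05 and 3 past in DESeq2, 6 lower adjusted over the list alone; median -1.30, camera adjusted p = 0.00118; adjusted p = 0.512 with an estimated correlation). DNAJB1 had -3.06 (adjusted p = 0.0596) and HSPH1 -2.60 (adjusted p = 0.0586), and both passed with the animal as a block (-2.09, adjusted p = 0.0175, and -2.06, adjusted p = 0.00424). The mean log2 CPM of the list in B cells before transplantation was 8.19 in R176 and 9.30 in R178 against 6.73 in R175 and 6.52 in R182, and 6.27 to 6.85 after it (exact permutation p = 0.2).

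Interferon response genes rose in B cells, with 4 of 26 members higher (7 adjusted over the list alone), a median log2 fold change of 0.51 and a camera adjusted p = 1.19e-05 (adjusted p = 0.213 with an estimated correlation). Among them were IRF7, a regulator of interferon genes (1.08, SE 0.22), the antiviral GTPase MX2 (0.97, SE 0.20) and the apoptosis-linked XAF1 (1.30, SE 0.32), with edgeR adjusted p from 0.0233 to 0.0478. Each of these 3 lost the call in 6 or more of the 8 leave-outs, with adjusted p up to 0.135 for XAF1 without post R178, 0.0863 for MX2 without post R178 and 0.0625 for IRF7 without post R175. The list of atypical memory genes did not pass (16 measured, 0 past in edgeR and 0 adjusted over the list alone, 3 at an unadjusted p under 0.05 and 0 past in DESeq2, median -0.42, camera adjusted p = 0.165; adjusted p = 0.692 with an estimated correlation). FCRL3 had -1.30 (adjusted p = 0.118; with the animal as a block -1.31, adjusted p = 0.0105), FGR -0.67 and ITGAX -0.60. The atypical memory list passed without pre R176 (camera adjusted p = 0.00984) and without post R182 (0.0141). Homing genes (median -0.53, camera adjusted p = 0.0680; adjusted p = 0.355 with an estimated correlation) held 3 lower and 1 higher of 15 (6 and 3 adjusted over the list alone), among them S1PR1, which guides egress from lymphoid tissue (-1.61), the receptor GPR18 (-1.59), CXCR5 and the integrin ITGA4 (0.71). The homing list passed without pre R175 (camera adjusted p = 0.0111), pre R176 (0.0415), post R176 (0.0476) and post R178 (0.0412). B cell receptor signalling genes had 2 of 24 lower (3 adjusted over the list alone; median -0.01, camera adjusted p = 0.50; adjusted p = 0.772 with an estimated correlation), the kinase LYN (-0.88) and RASGRP3 (-1.19), with CD79A at -0.55 (adjusted p = 0.0641; with the block -0.56, adjusted p = 0.0176). MHC class II genes had 0 of 10 past in edgeR and 0 adjusted over the list alone (2 at an unadjusted p under 0.05 and 1 past in DESeq2, median 0.10, mean 0.01, camera direction down, adjusted p = 0.901; adjusted p = 0.921 with an estimated correlation). IFI30 had -0.59 (with the block -0.55, adjusted p = 0.0254) and CIITA 0.49. Of the lists of other cell types, the cytotoxic and the monocyte lists passed camera in B cells at the preset correlation. The marker lists of T cells, NK cells and platelets did not (camera adjusted p = 0.711, 0.165 and 0.321). The cytotoxic list had a median of -0.95 in B cells (0 of 8 past in edgeR, 5 at an unadjusted p under 0.05 and 2 past in DESeq2, 5 lower adjusted over the list alone, camera adjusted p = 0.000625; adjusted p = 0.213 with an estimated correlation). GNLY had -1.55 and GZMB -0.87, and both passed with the block (-1.43, adjusted p = 0.00962, and -0.84, adjusted p = 0.0184). The monocyte alarmin list had a median of 1.01 (0 of 4 past in edgeR, 3 at an unadjusted p under 0.05 and 0 past in DESeq2, 3 higher adjusted over the list alone, camera adjusted p = 0.00872; adjusted p = 0.213 with an estimated correlation). S100A9 had 1.26 (with the block 1.35, adjusted p = 0.0247) and S100A8 0.84.

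In the atypical memory-like cluster, FOSB, an AP-1 subunit, fell by 1.80 (SE 0.24), from 639 to 172 CPM (edgeR adjusted p = 0.00364, n = 4 per time point). TAGAP, a gene of activated lymphocytes, fell by 3.21 (SE 0.52), from 113 to 18.5 CPM, CD83 by 1.67 (SE 0.28), and CSRNP1, NR4A2 and BCL2A1 by 1.31, 1.20 and 1.14. TM9SF1 rose by 1.29 (SE 0.24). In all, 11 of 2608 genes passed, 3 higher and 8 lower, against 263 at an unadjusted p under 0.05 and 51 with the animal as a block (17 higher and 34 lower). Falls did not outnumber rises without pre R175, pre R178 or post R178 (2 and 2 each), without post R176 (2 higher and 1 lower) and without post R182 (3 and 2). Of the immediate-early genes 1 of 13 was lower (4 adjusted over the list alone; median -0.72, camera adjusted p = 4.21e-09; adjusted p = 0.226 with an estimated correlation). KLF6 had -1.03 (adjusted p = 0.113; with the block -1.02, adjusted p = 0.00112). B cell activation genes had 2 of 5 lower (4 adjusted over the list alone; median -0.88, camera adjusted p = 1.54e-08; adjusted p = 0.171 with an estimated correlation), and noncanonical NF-kB and survival genes 1 of 6 lower (2 adjusted over the list alone; median -0.69, camera adjusted p = 0.000173; adjusted p = 0.171 with an estimated correlation). MCL1 had -0.72. The homing list had 0 of 9 past in edgeR (3 at an unadjusted p under 0.05 and 0 past in DESeq2, 2 lower adjusted over the list alone; median -0.24, camera adjusted p = 0.00325; adjusted p = 0.213 with an estimated correlation). GPR18 had -1.71 (adjusted p = 0.155; with the block -1.52, adjusted p = 0.0184). The list lost its call without pre R182 (adjusted p = 0.0955). Counts without a specimen were 4, 5, 4 and 7 for pre R175, R176, R178 and R182 and 13, 3, 4 and 5 for post R175, R176, R178 and R182. Only FOSB of the named genes kept its call throughout, and 5, 4, 5 and 3 named genes lost it in that order before transplantation (highest adjusted p 0.147, 0.0959, 0.113 and 0.0836) and 3, 6, 5 and 5 after it (0.110, 0.138, 0.138 and 0.122).

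Naive-like B cells were held mostly by cluster 3 before and cluster 6 after transplantation. They showed CD9 lower by 3.97 (SE 0.37) on the log2 scale, from 227 to 19.9 CPM (edgeR adjusted p = 3.56e-05, n = 4 per time point). ATF3 fell by 4.31, SOX4, a factor of immature lymphocytes, by 3.02, NFKBID by 2.84 and ETS2 by 2.39. CD86, a costimulatory ligand for T cells, rose by 2.13 (SE 0.34), from 14.2 to 57.5 CPM, together with CITED2 (2.16), GLIPR2 (2.03), CFD (1.70) and TRAF3IP3 (1.58). In all, 419 of 5745 genes passed, 192 higher and 227 lower, and 858 with the animal as a block (405 higher and 453 lower). Immediate-early genes had 8 of 17 lower (12 lower and 1 higher adjusted over the list alone; median -0.83, camera adjusted p = 1.18e-08; adjusted p = 0.251 with an estimated correlation). Members past the threshold included CD69 (-1.89) and FOSB (-1.6). B cell activation genes had 3 of 10 lower and 1 higher (8 and 1 adjusted over the list alone; median -0.95, camera adjusted p = 9.7e-06; adjusted p = 0.171 with an estimated correlation). CD83 had -2.21 and NR4A1 -2.01. Heat shock genes had 4 of 8 lower (5 adjusted over the list alone; median -1.56, camera adjusted p = 0.00162; adjusted p = 0.486 with an estimated correlation). Members past the threshold included DNAJB1 (-3.17), HSPH1 (-2.81) and HSP90AA1 (-1.98). The mean log2 CPM of the heat shock list before transplantation was 9.59 in R176 and 10.4 in R178, while 7.78 in R175 and 7.48 in R182 lay within the 6.99 to 8.06 after it (exact permutation p = 0.2). Interferon genes had 2 of 20 higher (3 adjusted over the list alone; median 0.40, camera adjusted p = 0.00237; adjusted p = 0.217 with an estimated correlation), MX2 (1.65) and IRF7 (1.09). Leaving out a specimen gave 270, 183, 237 and 509 for pre R175, R176, R178 and R182 and 261, 155, 231 and 329 for post R175, R176, R178 and R182. Of the 10 named by size only CITED2 lost its call, without post R176 (adjusted p = 0.0597), while HSP90AA1, HSPH1, DNAJB1 and IRF7 each lost theirs in 5 or more leave-outs. The named genes that lost the call numbered 1, 5 and 6 without pre R175, R176 and R178 (highest adjusted p 0.0948, 0.0931 and 0.128) and 5, 6, 5 and 5 without post R175, R176, R178 and R182 (0.0780, 0.140, 0.0974 and 0.0923).

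CD4 T cells, helper T cells, expressed more of several interferon-induced genes after transplantation and less of FOSB, ZFP36 and FOS among the immediate-early genes. GBP3, a guanylate-binding protein, rose by 1.24 (SE 0.18), APOL6, an apolipoprotein L gene, by 1.11 (SE 0.17), UBE2L6, an enzyme of ISG15 conjugation, by 0.99 (SE 0.13) and TRAF3IP3 by 1.23 (SE 0.23). FOSB fell by 1.72 (SE 0.20), NR4A2 by 1.63 (SE 0.18), the heat shock gene HSPH1 by 1.91, the corepressor TLE1 by 1.91 and YIPF5 by 1.57 (edgeR adjusted p of these 9 genes from 0.00300 to 0.0295, n = 4 per time point). In all, 493 of 9118 genes passed, 188 higher and 305 lower, and 1239 with the animal as a block (497 higher and 742 lower). Interferon genes had 7 of 29 higher (13 adjusted over the list alone; median 0.59, camera adjusted p = 5.82e-09; adjusted p = 0.251 with an estimated correlation). Members past the threshold included MX2 (1.67), IRF7 (1.22) and DTX3L (0.83). Immediate-early genes had 3 of 18 lower (8 adjusted over the list alone; median -0.64, camera adjusted p = 3.71e-06; adjusted p = 0.408 with an estimated correlation). ZFP36 had -0.97 and FOS -1.02. Ribosomal protein genes had 10 of 83 lower and 1 higher (17 and 2 adjusted over the list alone; median -0.18, camera adjusted p = 1.66e-05; adjusted p = 0.607 with an estimated correlation). RPL31 had -0.74. The mean log2 CPM of the list was lowest in post R182, at 10.8 against 10.9 to 11.3 in the other specimens (exact permutation p = 0.114). Beside these, B cell markers were lower in CD4 T cells, 2 of 5 (3 adjusted over the list alone; median -0.93, camera adjusted p = 0.00182; adjusted p = 0.213 with an estimated correlation), and monocyte markers higher, 3 of 11 (4 higher and 1 lower adjusted over the list alone; median 0.74, camera adjusted p = 0.00284; adjusted p = 0.217 with an estimated correlation). CD79A had -0.93, MS4A1 -1.22, LYZ 0.95 and S100A9 1.20. CXCR5, also a receptor of follicular helper T cells, fell by 1.68 (SE 0.34, adjusted p = 0.0191). Leaving out 1 specimen at a time gave 163, 251, 218 and 419 for pre R175, R176, R178 and R182 and 502, 137, 99 and 301 for post R175, R176, R178 and R182. Named genes that lost the call numbered 13, 11 and 11 without pre R175, R176 and R178 (highest adjusted p 0.0988, 0.0948 and 0.119) and 2, 14, 18 and 10 without post R175, R176, R178 and R182 (0.0586, 0.114, 0.139 and 0.0846), among them HSPH1 and TRAF3IP3.

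CD8 T cells, the cytotoxic T cells, showed falls of ATF3 by 3.0 (SE 0.51), CD83 by 2.06 (SE 0.29), the cell cycle inhibitor CDKN1A by 1.94 (SE 0.25), FOSB by 1.79 and RGCC by 1.68. APOL6 rose by 1.72 (SE 0.23), APOL2 by 1.56 (SE 0.22), CFD by 1.37 (SE 0.18), the major vault protein gene MVP by 1.24 and DPP4, a surface peptidase of activated T cells, by 1.21 (edgeR adjusted p of these 10 from 0.00911 to 0.0451, n = 4 per time point). In all, 92 of 7406 genes passed, 30 higher and 62 lower, and 348 with the animal as a block (124 higher and 224 lower). Rises outnumbered falls without pre R176 (5 and 4), post R178 (8 and 5) and post R182 (27 and 23). Immediate-early genes had 2 of 17 lower (10 adjusted over the list alone; median -0.97, camera adjusted p = 5.93e-11; adjusted p = 0.319 with an estimated correlation), and interferon genes 3 of 25 higher (12 higher and 1 lower adjusted over the list alone; median 0.49, camera adjusted p = 3.5e-07; adjusted p = 0.171 with an estimated correlation), among them OAS2 (1.82) and DTX3L (1.14). The cytotoxic list had 0 of 18 past in edgeR (4 at an unadjusted p under 0.05 and 3 past in DESeq2, 3 higher adjusted over the list alone; median 0.27, camera adjusted p = 0.0405; adjusted p = 0.35 with an estimated correlation). TBX21 had 1.41 and KLRD1 0.92 (adjusted p = 0.0667 each), and both passed with the block (1.52, adjusted p = 0.0183, and 0.87, adjusted p = 0.0235). The list lost its call without pre R176 (0.0801), pre R182 (0.103) and post R175 (0.132). Counts without a specimen were 9, 9, 13 and 41 for pre R175, R176, R178 and R182 and 85, 47, 13 and 50 for post R175, R176, R178 and R182. Named genes that lost the call numbered 7, 8, 8 and 6 in that order before transplantation (highest adjusted p 0.112, 0.125, 0.105 and 0.0742) and 3, 7 and 1 without post R176, R178 and R182 (0.0657, 0.138 and 0.0867). APOL6, APOL2, CD83, CDKN1A and CFD kept it throughout.

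NK cells showed CCL4L1, a chemokine gene of the CCL4 family whose near-identical copies make its counts uncertain, lower by 2.41 (SE 0.22), from 388 to 69.6 CPM (edgeR adjusted p = 7.21e-05, n = 4 per time point). FOSB fell by 1.71 (SE 0.26), the oxidative stress factor NFE2L2 by 2.16, HSPH1 by 1.94, SERTAD2 by 1.94 and CCNH by 1.83. The actin-binding COTL1 rose by 2.02 (SE 0.40), with APOL6 (1.97), APOBEC3G (1.52) and CRELD2, a chaperone of the endoplasmic reticulum (1.47). In all, 73 of 3986 genes passed, 41 higher and 32 lower, and 295 with the animal as a block, where falls outnumbered rises (139 higher and 156 lower). They also did without a filter on genes (53 higher and 144 lower), without pre R182 (61 and 75) and without post R175 (16 and 18). Immediate-early genes had 3 of 13 lower (9 adjusted over the list alone; median -0.97, camera adjusted p = 8.96e-10; adjusted p = 0.251 with an estimated correlation). These included BTG2 (-1.50) and FOS (-1.33). Interferon genes had 1 of 15 higher (5 adjusted over the list alone; median 0.46, camera adjusted p = 9.64e-05; adjusted p = 0.190 with an estimated correlation). With a specimen left out the counts were 16, 15, 26 and 136 for pre R175, R176, R178 and R182 and 34, 21, 8 and 34 for post R175, R176, R178 and R182. Only CCL4L1 and FOSB of the named genes kept their calls throughout, and 10, 11 and 9 lost them without pre R175, R176 and R178 (highest adjusted p 0.0990, 0.106 and 0.0907) and 8, 11, 15 and 7 without post R175, R176, R178 and R182 (0.103, 0.154, 0.110 and 0.0955).

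CD14 monocyte-like cells expressed more of 5 interferon-induced genes after transplantation. APOL6 rose by 3.0 (SE 0.48), from 14.3 to 123 CPM, GBP7 by 2.21 (SE 0.38), IRF7 by 2.06 (SE 0.41), EPSTI1 by 2.04 (SE 0.46) and GBP3 by 1.57 (SE 0.30). The interferon list had 2 of 30 members higher (12 adjusted over the list alone; median 1.12, camera adjusted p = 2.3e-12; adjusted p = 0.361 with an estimated correlation). The mean log2 CPM of the list after transplantation was 7.09 in R182 against 4.99 to 5.77 in the other animals, and its difference between the time points had an exact permutation p = 0.0571. TNFSF13B, which encodes BAFF, the target of belimumab, rose by 0.82 (SE 0.18, edgeR adjusted p = 0.0401, n = 4 per time point), from 119 to 210 CPM. Immediate-early genes had 5 of 17 lower (8 lower and 1 higher adjusted over the list alone; median -0.72, camera adjusted p = 5.13e-08; adjusted p = 0.150 with an estimated correlation). Members past the threshold included FOSB (-2.05) and RGS1 (-2.15). CYP1B1, a target of the aryl hydrocarbon receptor, fell by 4.86 (SE 0.91), from 382 to 12.8 CPM. In all, 219 of 8078 genes passed, 70 higher and 149 lower, and 455 with the animal as a block (174 higher and 281 lower). Without a specimen the counts were 163, 64, 70 and 337 for pre R175, R176, R178 and R182 and 122, 117, 42 and 255 for post R175, R176, R178 and R182, of which 24, 6 and 8 were higher without pre R175, R176 and R178. Named genes that lost the call numbered 5, 9, 8 and 1 in that order before transplantation (highest adjusted p 0.0904, 0.131, 0.116 and 0.0539) and 9, 5, 14 and 3 after it (0.0969, 0.0920, 0.118 and 0.0553), among them TNFSF13B, lost in 6 of 8 leave-outs. Without the shallow cluster 491 genes passed (218 shared).

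The other large falls in these monocytes were of B cell genes: IGKC, the immunoglobulin kappa constant gene, fell by 5.79 (SE 0.78), from 236 to 3.97 CPM, MS4A1, which encodes CD20, by 5.30 (SE 0.66), from 122 to 2.93 CPM, CD79B by 4.56 and IGHM by 4.44 (edgeR adjusted p from 0.00530 to 0.0139, n = 4 per time point). B cell markers had 6 of 7 lower (7 adjusted over the list alone; median -4.01, camera adjusted p = 3.52e-12; adjusted p = 0.213 with an estimated correlation), and T cell markers 3 of 7 lower (7 adjusted over the list alone; median -2.21, camera adjusted p = 1.16e-07; adjusted p = 0.251 with an estimated correlation). These included the T cell kinase LCK (-2.57) and CD3G (-2.16). At least 3 UMIs from a fixed set of B cell genes, among them MS4A1, CD79A and CD79B, were present in 3.47%, 20.1%, 18.3% and 2.87% of these cells before transplantation, in R175, R176, R178 and R182, and in 0.221%, 0.324%, 0.187% and 0.199% after it (exact permutation p = 0.0286). T cell UMIs were present in 5.66% and 0.599% on average (exact permutation p = 0.0286). When the cells carrying either were left out, 102 of 7318 tested genes passed (89 shared). Among the named genes 11 kept the call, APOL6 among them, and the calls not counted here could not be compared. The 4 that lost it were TNFSF13B (0.66, adjusted p = 0.0861), EPSTI1 (1.89, adjusted p = 0.0694), IGHM (-1.42, adjusted p = 0.152) and CD22 (-1.21, adjusted p = 0.238). CD79B and IGHM also lost their calls without post R178 (adjusted p = 0.0614 and 0.0626).

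**Figure D4:**
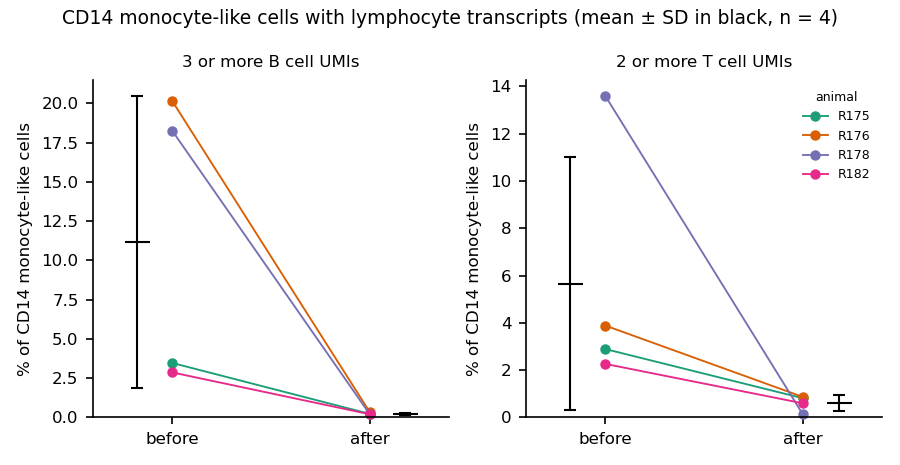
Percent of CD14 monocyte-like cells (vertical axis) with at least 3 B cell UMIs and with at least 2 T cell UMIs, before and after transplantation. Points are animals, lines join the same animal and black marks give the mean ± SD (n = 4); the mean for B cell UMIs was 11.2% before and 0.233% after.

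CD16 monocyte-like cells, the nonclassical monocytes, showed KLF4, a factor of monocyte differentiation, lower by 1.73 (SE 0.26, edgeR adjusted p = 0.0427) and TIPARP, another aryl hydrocarbon receptor target, lower by 1.48 (SE 0.19, adjusted p = 0.0190). The third and last call of 6579 tested genes, the unnamed ENSMMUG00000055690 (1.35, adjusted p = 0.0108), lay outside the rule for named genes and was chosen after its value was seen. Post R182 had 7 such cells and was not used, so 4 values were compared with 3, and 975 genes had an unadjusted p under 0.05, 61 passed in DESeq2 and 117 with the animal as a block (36 higher and 81 lower). Immediate-early genes had 1 of 17 lower (11 adjusted over the list alone; median -1.05, camera adjusted p = 3.73e-12; adjusted p = 0.244 with an estimated correlation), and interferon genes 0 of 25 past in edgeR and 0 adjusted over the list alone (9 at an unadjusted p under 0.05 and 0 past in DESeq2, median 0.68, camera adjusted p = 5.36e-06; adjusted p = 0.362 with an estimated correlation). The mean log2 CPM of the interferon list in pre R182 (6.09) lay above post R176 (5.63) and post R178 (5.99), with an exact permutation p = 0.143. Counts were 0, 0, 2 and 3 without pre R175, R176, R178 and R182 and 1, 8 and 10 without post R175, R176 and R178. KLF4 lost its call without pre R175 (0.18), R176 (0.188), R178 (0.124) and post R175 (0.0808), and TIPARP without pre R175 (0.0763), R176 (0.179) and post R175 (0.0778).

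Dendritic-like cells, which present antigen to T cells, showed falls of several inflammatory genes. IL1B, the cytokine interleukin-1 beta, fell by 2.47 (SE 0.44), from 1151 to 200 CPM, EGR2 by 3.24 (SE 0.48), the sterol regulator INSIG1 by 2.66 (SE 0.53), RGCC by 2.57 (SE 0.40) and the phosphatase DUSP10 by 2.26 (SE 0.34), with edgeR adjusted p from 0.0149 to 0.0448 (n = 4 per time point). TNF and NF-kB response genes had 3 of 12 lower (5 adjusted over the list alone; median -1.05, camera adjusted p = 1.01e-08; adjusted p = 0.213 with an estimated correlation), IL1B, NFKBIA (-1.70) and TNFAIP3 (-1.80), with PTGS2 at -2.71 (adjusted p = 0.0725; with the block -2.81, adjusted p = 0.0103). Immediate-early genes had 3 of 17 lower (10 adjusted over the list alone; median -0.81, camera adjusted p = 4.77e-10; adjusted p = 0.217 with an estimated correlation). Members past the threshold included FOSB (-1.79). Interferon genes had 0 of 12 past in edgeR (9 at an unadjusted p under 0.05 and 2 past in DESeq2, 9 higher adjusted over the list alone; median 1.35, camera adjusted p = 9.35e-07; adjusted p = 0.319 with an estimated correlation). ISG15 had 2.48 and IRF7 2.20, and both passed with the block (1.89, adjusted p = 0.0298, and 1.91, adjusted p = 0.0013). The mean log2 CPM of the interferon list after transplantation was 8.11 in R182 against 6.17 to 6.84 in the other animals (exact permutation p = 0.0571). The value of pre R182 (6.53) lay above that of post R176. The TNF and NF-kB list stood at 5.10 in post R182 against 6.51 to 6.82 in the other post specimens (exact permutation p = 0.0286). In all, 35 of 3752 genes passed, 4 higher and 31 lower, and 172 with the animal as a block, where the split was less one-sided (72 higher and 100 lower), as it was without a filter on genes (83 and 162). Counts with 1 specimen left out were 0, 1, 25 and 29 for pre R175, R176, R178 and R182 and 6, 16, 1 and 31 for post R175, R176, R178 and R182, against 607 genes at an unadjusted p under 0.05 and 67 in DESeq2 with all specimens. Each named gene lost its call in at least 1 leave-out, 9, 9, 2 and 1 in that order before transplantation (highest adjusted p 0.0991, 0.140, 0.10 and 0.0568) and 9, 7, 10 and 2 after it (0.110, 0.0928, 0.179 and 0.0634).

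Across the classes, immediate-early genes were past the camera threshold as lower in 9 of 9 and interferon genes as higher in 8 of 8 classes measured. The naive-like and atypical memory-like classes are parts of the B cells, so these counts of classes cover some cells more than once. B cell activation genes were lower in 8 of 9, NFAT targets in 7 of 7, and heat shock genes, TNF and NF-kB response genes and noncanonical NF-kB genes each in 7 of 9. Ribosomal protein genes were lower in 6 of 9. Several of these lists share members, so their falls are not separate results. NR4A1 stands in the immediate-early, B cell activation and NFAT lists. BCL2A1 stands in the lists of B cell activation, TNF and NF-kB response and noncanonical NF-kB genes. For immediate-early genes the real grouping gave the lowest p of 35 groupings in 2 of the 9 classes. Up to 9 groupings gave a p as small. For interferon genes it did so in 1 of the 8, and up to 10 groupings gave a p as small. Pre R178 had the highest mean log2 CPM of heat shock genes in all 9 classes. The exact permutation p of that list was 0.0857 to 0.429. Of 35 groupings 11 to 24 gave a p as small in the 7 classes past the threshold. Without pre R178 the list passed in 4 of 9. Post R182, the shallowest specimen, had the lowest mean of ribosomal protein genes in the 8 classes that used it. That list had an exact permutation p of 0.0286 in naive-like B cells and 0.114 to 0.2 in the other 5 classes past the threshold. Of 35 groupings 4 to 19 gave a p as small there. Without post R182 it passed in 3 of 8. Noncanonical NF-kB genes and TNF and NF-kB response genes passed in 5 to 8 classes with a specimen left out. Of 238 tests 95 passed, 18 higher and 77 lower, and 0 passed with an estimated correlation, where 45 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0548. Another assignment of the 8 specimens to 2 groups gave 90 calls in the 8 classes with all specimens against 88 for the real one, so list counts of this size also arise from other groupings. The changes of 5 lists were compared between B cells and each of CD4 T, CD8 T, NK and CD14 monocyte-like cells. Of these 20 differences 0 passed the exact permutation test after adjustment (lowest adjusted p = 0.286). With 4 against 4 a difference can pass over 20 tests only if most of them reach the smallest p of 0.0286, so this count was nearly fixed by the design. An unadjusted p under 0.05 was found for 2, the TNF and NF-kB response genes falling further in B cells than in CD4 T cells (difference -0.43) and NK cells (-0.54), at exact permutation p = 0.0286 each.

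**Figure D5:**
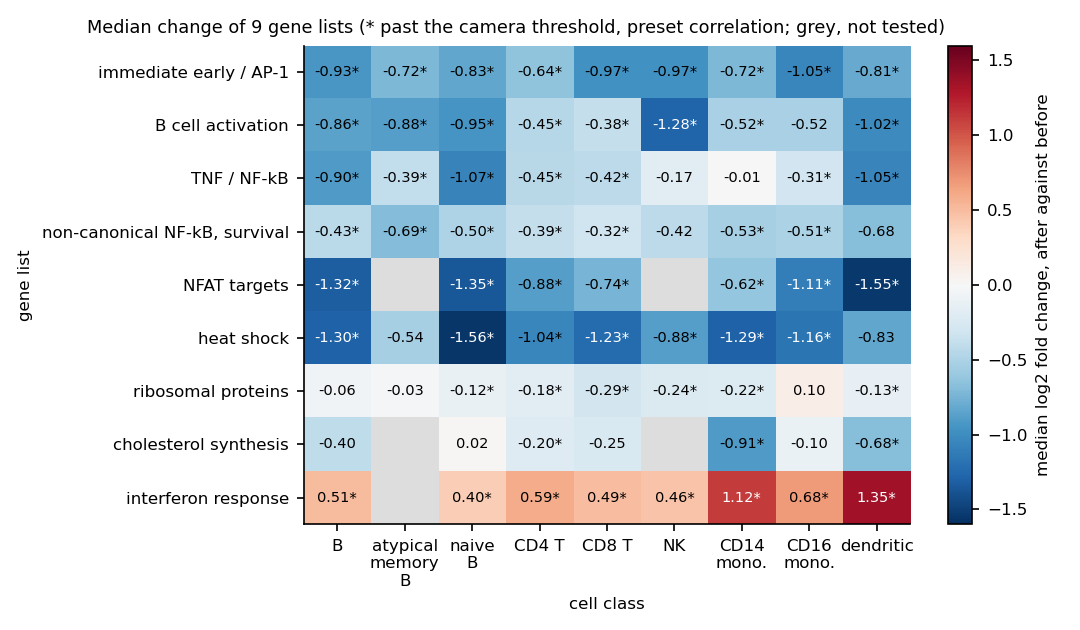
Median log2 fold change, post over pre, of 9 gene lists (vertical axis) in 9 classes (horizontal axis), coloured by value, with a star where camera passed the threshold at the preset correlation and grey where too few members were measured. Immediate-early genes ranged from -0.64 in CD4 T cells to -1.05 in CD16 monocyte-like cells; no star remained with an estimated correlation.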

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

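Of the tests in this part, those of the move of cells between B cell clusters were chosen before the result was seen, and the other tests of explanations after it. In 216 groups of 4 animals, 18 values lay far from the other 3, 8.33% of the groups, where chance gives about 1 in 20, and 2 of them were in post R182. In B cells the share with atypical memory markers was 3.34% in post R182 against 0.284% to 0.444% in the other post specimens, and the share with a CXCR5 UMI 7.37% in pre R182 against 4.94% to 5.29%. Also in B cells, TNFAIP3 stood at 62.5 CPM in post R175 (others 33.1 to 37.4), NR4A1 at 130 in post R175 (51.5 to 64.7), CFD at 63.4 in post R178 (49.5 to 50.8), TAF12 at 49.7 in post R176 (55.1 to 56.1), PTGES3 at 236.9 in pre R178 (171.4 to 174.7) and ZEB2 at 224.2 in pre R175 (150.9 to 158.7). CD83 stood at 237 CPM in atypical memory-like cells of post R175 (89.2 to 100), and CFD at 89.8 in naive-like cells of post R178 (56.3 to 61.6). In CD4 T cells HSPH1 stood at 432.4 CPM in pre R178 (99.1 to 141.4), TLE1 at 21.9 in post R178 (13.8 to 14.5) and TRAF3IP3 at 26.6 in post R175 (58.4 to 65.0). CDKN1A stood at 10 CPM in CD8 T cells of post R182 (20.2 to 21.7), APOBEC3G at 320.9 in NK cells of post R178 (186.6 to 206.8) and EGR2 at 111.9 in dendritic-like cells of pre R176 (44.3 to 46.4). In CD14 monocyte-like cells CYP1B1 stood at 1116 CPM in pre R182 (80.9 to 234.2) and TNFSF13B at 87.9 in pre R176 (127.5 to 133.1). Barcodes with tags of more than 1 animal, which no comparison used, made up 17.8% of tagged barcodes before and 20.3% after transplantation.

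The list of immediate-early genes passed camera as lower in all 9 classes, which count parts of the B cells beside the B cells, at the preset correlation. It passed in 0 with an estimated one, with 1 to 8 members past per class. The exact permutation p of its mean per animal was 0.0286 in B and CD14 monocyte-like cells and 0.0571 to 0.0857 in the others. Fewer cells of the activated-like clusters would leave the genes unmoved within other B cells, but their median log2 fold change was -0.72 or lower within both naive-like and atypical memory-like cells. The naive-like cells lay mostly in cluster 3 before and cluster 6 after transplantation. A move of cells between these clusters is therefore not set aside by the naive-like value. Summed counts were already scaled, and thinning keeps the expected share of each gene in a cell, so thinned B cells cannot test depth itself. Thinning only gives each cell the same weight in the sums. The median was -0.95 there, so the fall did not rest on a greater weight of deep cells. The handling of the 2 libraries, such as warming or delay before capture, would move the genes in every class, as seen in 9, and cannot be told apart from the treatment, because each time point had its own library. An effect of transplantation or immunosuppression stays open too and was not tested.

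B cell transcripts in CD14 monocyte-like cells were frequent before transplantation, above all in R176 and R178. Free RNA would reach other cells of a library alike, but as many B cell UMIs were present in 0.0322% of CD8 T, 0.458% of NK and 1.12% of CD16 monocyte-like cells on average (at median depths of 1478, 1698 and 2532 UMIs), against 11.2% of CD14 monocyte-like cells. The gap was narrow in R175, with 1.30% of NK and 1.22% of CD16 monocyte-like cells against 3.47%, so free RNA is less set aside in that animal. Doublets of a monocyte and a B cell would hold more UMIs, and the monocytes with B cell UMIs had 2.0, 2.48, 2.72 and 1.84 times the median UMIs of the others in R175, R176, R178 and R182. Deep cells reach 3 UMIs more easily, however, and draws by depth alone had upper limits of 1.96, 2.32, 2.77 and 2.26, so the ratio lay above them in only 2 of 4 animals. The pool of these draws included the cells with B cell UMIs. Their depth can raise the limits where such cells are frequent, as in R176 and R178. Doublets of the same animal therefore stay open, and an association of monocytes with B cells in blood was not tested.

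CXCR5 was lower in B cells after transplantation. Free RNA would also raise it in CD8 T cells, where its mean before transplantation was 2.57 CPM, far below the drop of 65.9 CPM in B cells. With each animal's cluster makeup held as before transplantation the mean log2 ratio was -0.84 (SD 0.77, n = 4), with -0.61 in R175, -0.82 in R176, -0.05 in R178 and -1.89 in R182, against -1.12 without that step. This lies beyond the bound set in advance by less than its spread, so a move of cells between clusters stays open. A difference between the libraries stays open as well and cannot be told apart from the treatment, since CXCR5 also fell in CD4 T cells (log2 fold change -1.68) and in CD14 monocyte-like cells (-5.90), where B cell transcripts leave part of the CXCR5 signal of pre R182 unaccounted for.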

How the results depend on the processing

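Tests chosen after the result was seen were those with the automatic doublet threshold, in B cells of clusters shared by both time points, in CD14 monocyte-like cells without the shallow cluster or without lymphocyte transcripts, and the list tests without a specimen. Of 161 named gene calls, 161 kept direction and call with the animal as a block, 158 with DESeq2 and 160 each with RLE scaling and without a filter on genes, and 49 kept the call with each specimen left out in turn. Of the named calls in B cells, only 16 held in clusters shared by both time points, and 23 were lost. In thinned B cells 32 held and 6 were lost. Of 41 list calls described, 41 passed with the block, 36 with each specimen left out in turn and 0 with an estimated correlation. The block removed no call of a named gene or described list. It added calls for 47 of the 79 named genes without one, and those printed have their blocked value beside them. Apart from these, the NK cell share and the counts below it changed no call of a share, a named gene or a described list. Depth limited the atypical memory-like and dendritic-like classes, where 2608 and 3752 genes could be tested against 8839 in B cells. The cause of the changes below was not tested, except that fewer specimens leave fewer residual degrees of freedom.

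The NK cell share passed as a logit with the block (-1.36). Changes in direction were the platelet-like share (-0.303 points with at least 500 genes, -0.00909 without doublet removal, -0.0161 with the automatic doublet threshold, -0.146 at resolution 0.5, -0.154 on the logit scale with the block), the cycling share (-0.720 by marker score) and the naive-like share (2.66 at resolution 2.0, 1.39 by marker score). The share of atypical memory-like cells with a CXCR5 UMI passed without thinning (-8.85). In B cells of clusters shared by both time points, ITGAX (0.0414), TCL1A (0.0163), CD86 (-0.0771), FCRL5 (0.38) and FGR (0.0146) turned direction. None of these 5 had passed.

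Without a filter on genes, 484 genes passed in B cells, 35 in atypical memory-like, 319 in CD8 T, 197 in NK, 556 in CD14 monocyte-like, 244 in CD16 monocyte-like and 245 in dendritic-like cells. With the block 955 passed in B, 51 in atypical memory-like, 858 in naive-like, 1239 in CD4 T, 348 in CD8 T, 295 in NK, 455 in CD14 monocyte-like, 117 in CD16 monocyte-like and 172 in dendritic-like cells. DESeq2 gave 412 in B, 192 in CD8 T, 110 in NK, 413 in CD14 monocyte-like, 61 in CD16 monocyte-like and 67 in dendritic-like cells. B cells of clusters shared by both time points gave 28 and thinned B cells 94. CD14 monocyte-like cells gave 491 without the shallow cluster and 102 without lymphocyte transcripts.

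Leaving out specimens gave differences in share from -0.521 to 7.46 points for B cells, -9.61 to 1.08 for CD4 T cells, -8.37 to 0.595 for CD8 T cells, 0.772 to 4.45 for CD16 monocyte-like cells, 0.2 to 0.779 for dendritic-like cells, -0.336 to 0.266 for platelet-like cells, 0.0998 to 0.566 for cycling cells, -10.2 to -2.02 for atypical memory-like B cells, -9.21 to 3.79 for naive-like B cells, 19.7 to 24.4 for the JCHAIN-expressing B cell cluster and -4.10 to -2.35 for CXCR5 in atypical memory-like cells. Counts of genes ran from 17 to 321 in B cells, 3 to 13 in atypical memory-like, 155 to 509 in naive-like, 99 to 502 in CD4 T, 9 to 85 in CD8 T, 8 to 136 in NK, 42 to 337 in CD14 monocyte-like, 0 to 10 in CD16 monocyte-like and 0 to 31 in dendritic-like cells. The MHC class II list ran from -0.0561 to 0.0426, CD86 in B cells from -0.0780 to 0.58 and FCRL5 from -0.35 to 0.17.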

Other observations

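Of the tests in this part, the count of list calls over other groupings was chosen before the result was seen, and the counts of genes over other groupings after it. Genes of cholesterol synthesis fell in 3 of 7 classes by camera. In CD14 monocyte-like cells 2 of 12 members were lower (4 lower and 1 higher adjusted over the list alone; median -0.91, camera adjusted p = 0.00182; adjusted p = 0.217 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at -1.84 (SE 0.23). In CD4 T cells 4 of 13 were lower (4 adjusted over the list alone; median -0.20, camera adjusted p = 0.0151; adjusted p = 0.310 with an estimated correlation), including INSIG1 (-0.80) and IDI1 (-0.87), and the call was lost without post R182 (adjusted p = 0.0750). In dendritic-like cells 1 of 6 was lower (2 adjusted over the list alone; median -0.68, camera adjusted p = 0.0202; adjusted p = 0.217 with an estimated correlation), and the call was lost without post R176 (adjusted p = 0.0730).

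Naive-like B cells expressed more of several plasma cell genes. JCHAIN rose by 1.44 (SE 0.26), the endoplasmic reticulum factor DERL3 by 0.96 (SE 0.19) and the chaperone MZB1 by 0.77 (SE 0.18), while IRF4, a factor needed for plasma cell differentiation, had -0.77 (adjusted p = 0.0908; with the animal as a block -0.86, adjusted p = 0.00838). The list had 3 of 4 members higher (3 higher and 1 lower adjusted over the list alone; median 0.86, camera adjusted p = 0.00583; adjusted p = 0.213 with an estimated correlation). In NK cells genes of the unfolded protein response had 4 of 12 higher and 1 lower (4 and 1 adjusted over the list alone; median 0.38, camera adjusted p = 0.00305; adjusted p = 0.385 with an estimated correlation), with MANF at 1.07, PDIA6 at 0.80 and HERPUD1 at -0.88, and the call was lost without post R175 (adjusted p = 0.112). Over B, CD4 T, CD8 T, NK, CD14 monocyte-like and dendritic-like cells, 869 genes were called in any class, 219 in at least 2 and 28 in at least 4, of which 20 were lower and 8 higher. FOSB and RGCC were lower in 6 of these classes, and CSRNP1 and the repressor ETV3 in 5. The unnamed ENSMMUG00000055690 and ENSMMUG00000062077 were higher in 6, and ENSMMUG00000049855 and ENSMMUG00000062821 in 5. APOL6, CFD and the pyroptosis gene GSDMD were among those higher in 4.

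The 8 specimens can be parted into 4 and 4 in 35 ways, and 8 of these part all 4 animals, the real one among them. Over all 35, which leave the pairing by animal aside, only the real grouping gave as many genes in 8 classes. This share of 1 in 35 is the smallest possible. It was not adjusted over the 9 classes, so it does not by itself exclude chance. The counts were 270 against 11 at most in B, 11 against 10 in atypical memory-like, 419 against 5 in naive-like, 493 against 9 in CD4 T, 92 against 10 in CD8 T, 73 against 10 in NK, 219 against 5 in CD14 monocyte-like and 35 against 11 in dendritic-like cells. In CD16 monocyte-like cells, by contrast, 4 of 35 gave as many as the real 3, up to 10. Among the groupings that part all 4 animals the highest other count was 0 in each class, but 8 groupings are too few for a share under 0.05, so with the pairing chance was not tested to that level. Chance was not excluded for the lists either, since 3 of 35 groupings gave as many calls as the real 88 in the 8 classes with 8 specimens, with 90 for pre R175 with post R176, R178 and R182 against the rest, which also parts all 4 animals. Of the 95 list calls, 24 had their lowest p in the real grouping.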
